A study of Rattus norvegicus with 9 samples.

How the data were processed

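RNA was extracted from rat brain tissue with Trizol, and mRNA was selected by its poly(A) tail, fragmented, copied into cDNA and amplified by PCR into libraries, per the labels' protocols. The brain region, the hemisphere and the model are not given in the sources used here. The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, HISAT2 without a version and StringTie 1.3.1, without saying what each did. The counting step, the strand setting, the genome build and the annotation release are not given in the sources used here. The authors deposited 1 table of whole-number read counts per Ensembl rat gene and library, not normalized, and edgeR and the other count tests were run on these counts as deposited. Reads shared between near-identical or overlapping genes cannot be told apart in such counts, and without a stated strand setting neither can antisense pairs.

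Groups and replicate numbers came from the sample titles. The columns of the rt-PA libraries carry another name in the table, uk, and were matched to them through the sample descriptions, which also say uk. These libraries are called rt-PA here after their titles and treatment labels, and the differing name was not resolved. Each group had 3 libraries. The labels do not say that these came from separate animals, so p-values measure only the spread between these samples, which may be technical. Totals of 13059048 to 14992109 counts, with a median of 260 to 309.5 counts per tested gene and library, make counting error small for most genes beside the spread between libraries. The common biological coefficient of variation was 0.36.

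Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups, leaving 15402 of 32623, and library totals were scaled by TMM. All 9 libraries were fitted together with 1 mean per group and 6 residual degrees of freedom, and each contrast was tested with the robust quasi-likelihood F test. A further F test asked for any difference among the 3 groups. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called, with no fold threshold. Standard errors were the log2 fold change divided by the square root of F. Values per library are CPM with TMM scaling, and log2 CPM for correlations and principal components used a prior count of 2. For the gene with very low counts in 2 groups, the ratio of summed counts was given with an exact binomial interval, which covers counting error only. PCR duplicates are not independent molecules, so such intervals are too narrow. With 3 libraries against 3, an exact two-sided permutation test of a single gene cannot give a p below 0.1, so none was used.

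The designs, the alternatives and 44 gene lists were fixed before the data were examined. The lists were written as gene symbols, and the reference gene table used here, with 47357 genes, holds an Ensembl identifier for 0 of them, so 0 identifiers could be paired with a symbol. The lists were therefore not tested. The rule fixed for named genes, the 8 largest changes past the threshold in each direction per comparison and a set of symbols given in advance, could not be used either. In its place the 2 genes with the smallest unadjusted p in each direction over the 3 comparisons were named, among genes with a mean of at least 5 CPM. This choice was made after the values were seen.

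Alternatives were DESeq2 1.42.0, limma-voom and limma-voom with library weights in limma 3.58.1, relative log expression scaling, library totals alone, no filter on low counts, a filter of 1 CPM in 3 libraries, only the 6 libraries of a comparison, each library left out in turn, the replicate number as a block, a 2-fold threshold and an adjusted p under 0.01. After the data were examined, fits without saline 1, rt-PA 3 and Nano-patrol+NIR 3, fits of all 27 choices of 1 library left out per group, and fits with 1 or 2 surrogate variables from sva 3.50.0 were added.

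Each test was checked on counts simulated from the means, dispersions and totals of these libraries, with 50 genes changed at each fold. For rt-PA against saline, edgeR recovered 6% of genes changed 2-fold, 44% at 4-fold, 72% at 8-fold and 86% at 16-fold, with 5 false calls among 15201 genes. For Nano-patrol+NIR against saline the shares were 14%, 68%, 90% and 92%, with 5 false calls among 15205 genes. For Nano-patrol+NIR against rt-PA they were 4%, 66%, 92% and 90%, with 14 false calls among 15206 genes. In the same simulations DESeq2 made 51, 55 and 66 false calls. No simulated library was made to stand apart from its group, as single real libraries did. Among splits that mixed the real rt-PA and saline libraries, the highest count was 1507 with DESeq2. With limma-voom with library weights it was 6664. The simulated shares and false calls therefore may not hold for the real libraries.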

Results

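Gene expression was measured by RNA sequencing in brain tissue of rats given 1 of 3 treatments. The injection came 4.5 h after a modelling step that the labels do not describe. By their titles and treatment labels the groups received saline, rt-PA or Nano-patrol+NIR, and tissue was taken 3 days later. The count columns and sample descriptions of the rt-PA libraries say uk instead, so which agent this group received was not resolved. rt-PA, recombinant tissue plasminogen activator, dissolves clots by converting plasminogen to plasmin. The series title places Nano-patrol+NIR among thrombolysis treatments meant to carry a lower risk of bleeding, and the labels describe it no further. Each group had 3 libraries, named here by group and replicate number, and no group without the modelling step was analysed here. Nor was a group given Nano-patrol or NIR alone, so the parts of that treatment cannot be told apart. Library totals ran from 13059048 to 14992109 counts. The table listed 32623 Ensembl rat genes, of which 9763 had no count in any library and 15402 were abundant enough to be tested. The files do not pair these identifiers with gene symbols, and only 4 genes are named, by identifier.

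Expression across genes separated 1 library of each group from the other 2. Saline 2 and saline 3 correlated at r = 0.9903 over the log2 CPM (counts scaled to a common library total) of the tested genes, whereas saline 1 correlated with them at 0.9261 and 0.9307. rt-PA 1 and rt-PA 2 correlated at 0.9836, and rt-PA 3 with them at 0.913 and 0.8962. Nano-patrol+NIR 1 and 2 correlated at 0.9851, and Nano-patrol+NIR 3 with them at 0.9401 and 0.9441. These coefficients are across genes, which are not independent replicates. Among 11022 genes averaging at least 100 counts, 0.2% differed more than 2-fold between saline 2 and saline 3, and 15.8% between saline 1 and saline 2. The corresponding shares were 1.2% between rt-PA 1 and rt-PA 2 and 22.5% between rt-PA 2 and rt-PA 3. They were 0.9% between Nano-patrol+NIR 1 and 2 and 8.8% between Nano-patrol+NIR 1 and 3. No pair within a group agreed within counting noise (chi-square per degree of freedom of at least 9.43), so none looked like 1 library deposited again; this does not show that the libraries came from separate animals. Spread within each group therefore came mostly from a single library. These libraries were not alike in all respects, since on the third principal component (16.4% of variance) saline 1 lay at -75.2, and rt-PA 3 and Nano-patrol+NIR 3 at 26.7 and 33.3.

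**Figure D1:**
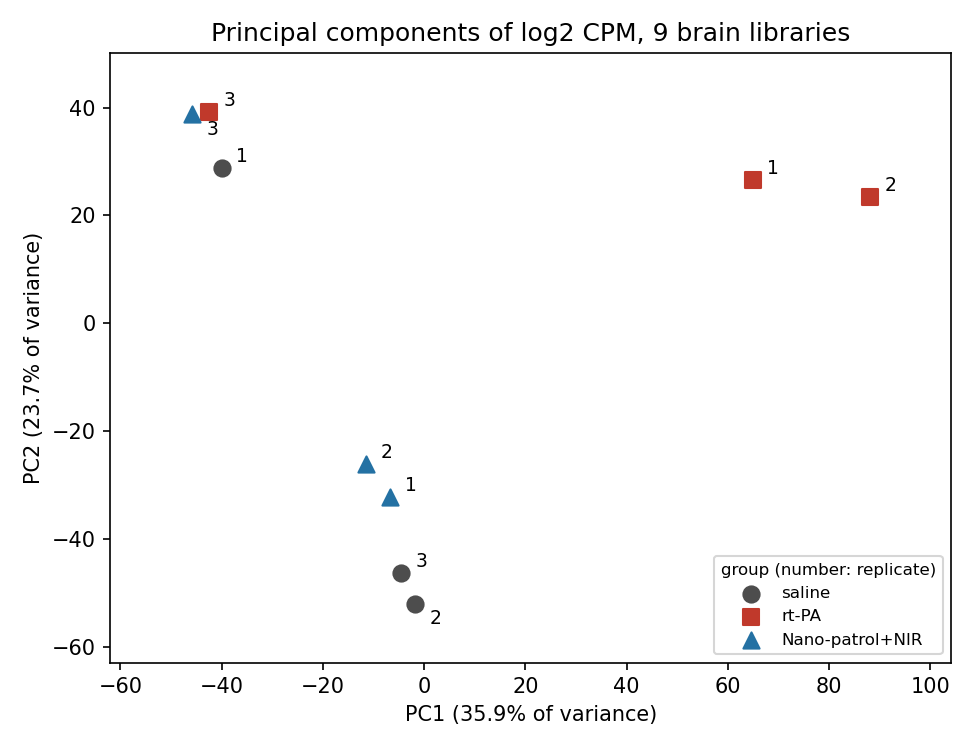
First and second principal components of the log2 CPM of the tested genes, with the share of variance on each axis; each point is 1 library, its shape and colour give the group and its number the replicate. rt-PA 1 and 2 lie at the right, saline 2 and 3 at the lower centre beside Nano-patrol+NIR 1 and 2, and saline 1, rt-PA 3 and Nano-patrol+NIR 3 together at the upper left.

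The first comparison asked how brain expression after rt-PA differed from that after saline. ENSRNOG00000012067 averaged 0.202 ± 0.161 CPM in rt-PA and 35.9 ± 11.4 CPM in saline (SD, n = 3 each), and was the 1 gene of 15402 past the threshold. Its log2 fold change was -7.43 (SE 0.56, edgeR adjusted p = 0.00662). The rt-PA libraries held 1 to 5 counts of this gene and 8 in all, against 1488 in the saline libraries. The ratio of saline to rt-PA, scaled by library totals, was 180 with an exact 95% interval of 90.9 to 417, which covers counting error only. Whether rt-PA lowered this gene or the saline samples differed in another way was not tested. ENSRNOG00000007830 averaged 58.4 ± 13.8 CPM in rt-PA and 18.4 ± 1.22 CPM in saline (SD, n = 3 each), a log2 difference of 1.66 (SE 0.2, edgeR adjusted p = 0.0594). ENSRNOG00000017897 averaged 31.4 ± 2.65 CPM in rt-PA and 11.3 ± 1.57 CPM in saline (SD, n = 3 each), a log2 difference of 1.48 (SE 0.17, edgeR adjusted p = 0.0594). ENSRNOG00000019737 averaged 112 ± 10.5 CPM in rt-PA and 56.4 ± 4.7 CPM in saline (SD, n = 3 each), a log2 difference of 0.99 (SE 0.14, edgeR adjusted p = 0.0594). These last 3 genes were higher in each rt-PA library than in any saline library, and missed the threshold of 0.05. The named genes were picked by their small p in these same libraries, so such separation follows partly from the choice. Over all tested genes, the named ones included, 2621 genes (17%) had an unadjusted p under 0.05, against 770 if p-values were spread evenly. Of these, 1394 were higher and 1227 lower in rt-PA. A mixed split of these libraries, rt-PA 1, rt-PA 2 and saline 1 against the rest, had more, 3085. The ranges of the groups did not overlap for 1414 genes higher and 1582 genes lower in rt-PA, together 19.5% of those tested, where chance gives 10%. The number of genes called depended on the test, being 1002 with DESeq2 (637 higher, 365 lower), 0 with limma-voom, which had 2384 at an unadjusted p under 0.05, and 6956 with limma-voom fitted with a weight per library (3367 higher, 3589 lower), so the direction of the majority depended on the test as well. Without rt-PA 3 edgeR called 2112 genes (1304 higher, 808 lower), without saline 1 it called 11 and without Nano-patrol+NIR 3 it called 2. The edgeR adjusted p of ENSRNOG00000012067 was 0.0566 without saline 2 (log2 fold change -7.34), 0.0519 without saline 3 (-7.2) and 0.118 without rt-PA 1 (-7.27). It was 0.0714 with only the 6 libraries compared (-7.43) and 0.0588 with the replicate number as a block (-7.46). With limma-voom the adjusted p was 0.0507 (-7.42).

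**Figure D2:**
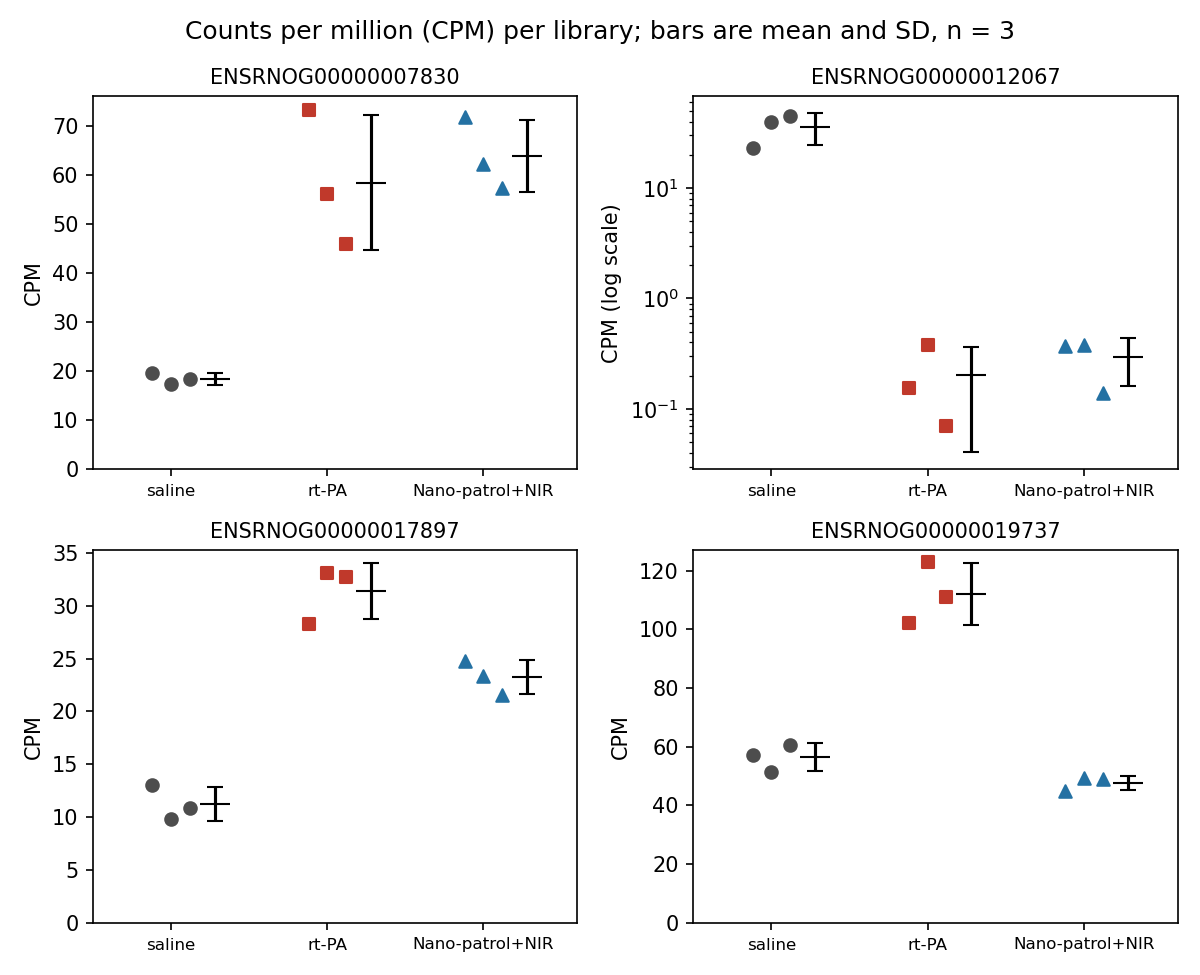
CPM of the 4 named genes in each library (points) with the mean and SD of each group (bars, n = 3); the axis of ENSRNOG00000012067 is logarithmic and the other axes start at 0. ENSRNOG00000012067 lies between 23.1 and 45.3 CPM in the saline libraries and at 0.381 CPM or less in the other libraries.

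Nano-patrol+NIR was compared with saline in the same way. ENSRNOG00000012067 again passed the threshold, at 0.297 ± 0.137 CPM in Nano-patrol+NIR against 35.9 ± 11.4 CPM in saline (SD, n = 3 each). Its log2 fold change was -6.89 (SE 0.54, edgeR adjusted p = 0.00871). The Nano-patrol+NIR libraries held 2 to 5 counts of it and 12 in all, a saline to Nano-patrol+NIR ratio of 119 with an exact 95% counting interval of 68 to 231. ENSRNOG00000007830 averaged 63.8 ± 7.31 CPM in Nano-patrol+NIR (SD, n = 3), a log2 difference from saline of 1.79 (SE 0.2, edgeR adjusted p = 0.0687). ENSRNOG00000017897 averaged 23.3 ± 1.64 CPM (SD, n = 3), a log2 difference from saline of 1.05 (SE 0.17, edgeR adjusted p = 0.164). ENSRNOG00000019737 averaged 47.7 ± 2.36 CPM (SD, n = 3), a log2 difference from saline of -0.24 (SE 0.14, edgeR adjusted p = 0.959). Across the genome this contrast held fewer small p-values than the rt-PA contrast, with 907 genes (5.9%) at an unadjusted p under 0.05 against 770 for an even spread. Of these, 530 were higher and 377 lower in Nano-patrol+NIR. The mixed split of Nano-patrol+NIR 1, saline 2 and saline 3 against the rest had 1758. The groups did not overlap for 1174 genes higher and 1057 lower, together 14.5%, where chance gives 10%. DESeq2 called 128 genes (85 higher, 43 lower), limma-voom 0, with 782 at an unadjusted p under 0.05, and limma-voom with library weights 909. Without rt-PA 3 in the joint fit edgeR called 35 genes. The edgeR adjusted p of ENSRNOG00000012067 was 0.0722 without saline 2 and 0.067 without saline 3. It was 0.125 without Nano-patrol+NIR 1, 0.124 without Nano-patrol+NIR 2 and 0.0725 without Nano-patrol+NIR 3. With the replicate number as a block it was 0.07, and with limma-voom the adjusted p was 0.104. The log2 fold changes in these fits were -7.1 to -6.54.

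**Figure D3:**
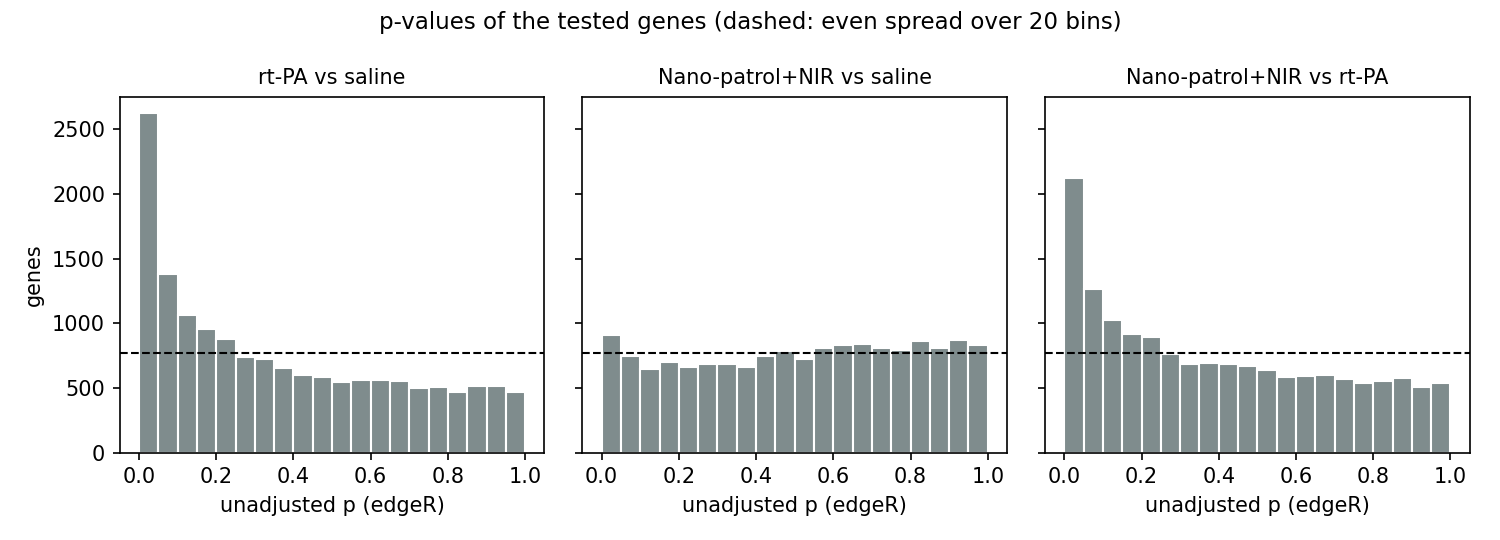
Numbers of tested genes (vertical axis) by unadjusted edgeR p (horizontal axis, 20 bins) in the 3 comparisons; the dashed line is the height of a bin if p-values were spread evenly. The first bin holds 2621 genes for rt-PA against saline, 907 for Nano-patrol+NIR against saline and 2121 for Nano-patrol+NIR against rt-PA.

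The direct comparison of both thrombolysis treatments asked whether expression differed between Nano-patrol+NIR and rt-PA. ENSRNOG00000019737 had the smallest p, averaging 47.7 ± 2.36 CPM in Nano-patrol+NIR and 112 ± 10.5 CPM in rt-PA (SD, n = 3 each). Each Nano-patrol+NIR library lay below each rt-PA library, with a log2 difference of -1.23 (SE 0.14), but the edgeR adjusted p of 0.0966 missed the threshold. ENSRNOG00000012067 was near the floor in both groups, at 0.297 and 0.202 CPM, and its difference was not detectable at this depth (edgeR adjusted p = 0.755). ENSRNOG00000007830 averaged 63.8 CPM in Nano-patrol+NIR and 58.4 CPM in rt-PA, with overlapping libraries and a log2 difference of 0.13 (SE 0.19, edgeR adjusted p = 0.803). ENSRNOG00000017897 averaged 23.3 CPM in Nano-patrol+NIR and 31.4 CPM in rt-PA, a log2 difference of -0.43 (SE 0.17, edgeR adjusted p = 0.306). No gene passed the threshold with edgeR, a count of 0, while 2121 genes (13.8%) had an unadjusted p under 0.05 against 770 for an even spread. Of these, 911 were higher and 1210 lower in Nano-patrol+NIR than in rt-PA. The mixed split of Nano-patrol+NIR 1, rt-PA 1 and rt-PA 2 against the rest had more, 2687. The groups did not overlap for 1369 genes higher and 1315 lower, together 17.4%, where chance gives 10%. DESeq2 called 601 genes (178 higher, 423 lower), limma-voom 1 and limma-voom with library weights 6027 (3113 higher, 2914 lower), so the direction of the majority depended on the test. Without rt-PA 3 edgeR called 2047 genes (783 higher, 1264 lower).

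In the test of all 3 groups together, ENSRNOG00000012067 alone passed the threshold, with an edgeR adjusted p of 0.00222, and 2270 genes had an unadjusted p under 0.05. DESeq2 called 1044 genes in this test, limma-voom 0, with 1975 at an unadjusted p under 0.05, and limma-voom with library weights 7624. edgeR called 1893 genes without rt-PA 3, 3 without saline 1 and 2 without Nano-patrol+NIR 3.

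Both treatments were set against the same saline libraries, which by itself makes their fold changes agree. Across 15402 genes the log2 fold changes of both contrasts correlated at r = 0.47, and simulated groups with no effect against shared controls gave 0.5. Their covariance was 0.168, against 0.11 in 20 simulations (SD 0.0033 between simulations), a difference of 0.0581. The simulations drew each gene and library independently, so no simulated library stood apart, and rt-PA 3 and Nano-patrol+NIR 3 were not alike in them. That SD does not cover the spread between real libraries. The difference therefore cannot tell a shared effect of the treatments from a likeness of single libraries. ENSRNOG00000012067 was the 1 gene called in both contrasts by edgeR, where independent lists of these sizes would share 6.5e-05 genes. The contrasts share the saline libraries, so their lists are not independent. In 10 simulations with no effect and shared controls, edgeR called means of 0.2 and 0 genes and 0 in both, too few to judge an overlap. DESeq2 called 57 genes in both contrasts. Of these, 42 were higher in both, against 3.19 for independent lists, and 14 were lower in both, against 0.925. In 10 simulations with no effect and shared controls, DESeq2 called means of 20.3 and 17 genes and 2.8 in both (1 to 7), but those lists were far shorter than the real ones. With 3 saline libraries the controls could not be split into 2 sets of at least 2, and how much of these overlaps comes from the shared controls is open. Without saline 3 the covariance difference was 0.0305, and without saline 1 it was 0.0986.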

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

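The fits without 1 library per group and those with surrogate variables were chosen after seeing the data. Numbers of called genes are given in the order rt-PA against saline, Nano-patrol+NIR against saline, Nano-patrol+NIR against rt-PA and any of the 3 groups, where edgeR gave 1, 1, 0 and 1. Relative log expression scaling, library totals alone, a filter of 1 CPM in 3 libraries, an adjusted p under 0.01 and, for the 3 pairwise comparisons, a 2-fold threshold left these numbers as they were. Without a filter on low counts the test of any group called 3, and the pairwise counts stayed at 1, 1 and 0. DESeq2 called 1002, 128, 601 and 1044, limma-voom 0, 0, 1 and 0, and limma-voom with library weights 6956, 909, 6027 and 7624. The weights were 0.18 for saline 1, 0.13 for rt-PA 3 and 0.31 for Nano-patrol+NIR 3, and 0.98 to 3.75 for the other libraries. Fitting only the 6 libraries compared gave 0, 3 and 0 for the pairwise comparisons. At an unadjusted p under 0.05 these fits held 2006, 1173 and 1918 genes, and limma-voom 2384, 782, 1897 and 1975.

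Leaving out each library in turn gave 0 to 2112, 0 to 35, 0 to 2047 and 1 to 1893 called genes. The highest value of each range came without rt-PA 3. Without saline 1, rt-PA 3 and Nano-patrol+NIR 3 edgeR called 6710, 501, 6195 and 6932. Those libraries were chosen because they lay farthest from their group, which makes the remaining spread and the p-values too small. Over the 27 choices of 1 library per group, rt-PA against saline gave 250 to 6710 calls in the 9 choices without rt-PA 3 and at most 1 in the 18 that kept it. Nano-patrol+NIR against rt-PA gave 160 to 6195 and 0, and Nano-patrol+NIR against saline 0 to 501 and at most 1, with 10 or more calls in 2 choices, 501 and 105. With 1 surrogate variable the numbers were 582 (264 higher, 318 lower), 5, 151 (98 higher, 53 lower) and 264, and with 2 they were 1799, 242, 690 and 1444.

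The replicate block called 0, 0, 0 and 1, with 2279, 741, 1865 and 1846 genes at an unadjusted p under 0.05. It gave ENSRNOG00000012067 adjusted p of 0.0588 and 0.07 against saline. Deviations from group means of same-numbered pairs correlated at -0.362 to 0.278, over 0.1 in 5 of 9. Of 9 libraries, 2 correlated best with their own number. In each group 1 library dominates these, so pairing stays open.

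ENSRNOG00000012067 kept its direction in all 21 alternatives. For rt-PA against saline its call held in 15 of them (log2 fold change -8.23 to -6.99, adjusted p 6.15e-27 to 0.118), and for Nano-patrol+NIR against saline in 14 (-7.11 to -6.54, 1.83e-29 to 0.125). The other 3 named genes kept their direction where their difference was largest. They passed the threshold in 4 to 7 of the 21. The covariance difference of 0.0581 was 0.0426 over genes of at least 5 mean CPM and 0.0305 to 0.0986 without 1 saline library. The cause of these changes was not tested. The gene lists were not tested under any setting, as no identifier had a symbol. No scaling moved the median log2 fold change of all genes by over 0.1. Depth limits the fold of ENSRNOG00000012067, with 1 to 5 counts per treated library.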

Other observations

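Of the tests below, the removal of the most abundant genes and the splits of all 9 libraries were set before their results were seen, and the others only afterwards.

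Few genes were switched on or off between libraries, and most of those followed single libraries and not treatments. Counting a gene as on at 2 CPM or more and as off at 5 counts or fewer, 106 genes were on in some libraries and off in all others. ENSRNOG00000012067, off in all rt-PA and Nano-patrol+NIR libraries, was the 1 gene on in the 3 saline libraries only. No gene was on in the 3 rt-PA libraries only, or in the 3 Nano-patrol+NIR libraries only, a count of 0 for each. Nano-patrol+NIR 3 alone held 41 of the genes, saline 1 alone 12 and rt-PA 3 alone 7, while 15 were on in rt-PA 3 and Nano-patrol+NIR 3 together.

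One library of each group, saline 1, rt-PA 3 and Nano-patrol+NIR 3, stood apart from the other 2, and their deviations from the group means correlated at 0.21 to 0.377 across genes. Their mean r with the 2 libraries of the alike pair was lower than the r within the pair by at least 0.043. Without the 100 most abundant genes it was lower by at least 0.0449. Library totals differed by at most 1.15 times, and keeping 0.5 of the counts of 1 library lowered the r of an alike pair by at most 0.0029. The fall on halving argues against depth as the cause. The r weighs each of 15402 genes equally, so removing 100 of them could hardly change it, and that test decides nothing. The 10 most abundant genes held 6.69 to 7.27% of the counts in the libraries apart and 5.22 to 8.46% in the others. In no library did a few genes take most of the counts. The highest r of a library apart with any library was 0.946, below the 0.9836 of the least alike close pair, so none joined the alike pair of another group. This limit cannot exclude exchanged labels, as Nano-patrol+NIR 3 itself reached 0.9401 and 0.9441 with Nano-patrol+NIR 1 and 2. rt-PA 3 reached 0.9404 and 0.9432 with that pair, and 0.913 and 0.8962 with rt-PA 1 and 2, so exchanged labels stay open. Different cells or a different piece of brain in those libraries may contribute. Of the 106 on or off genes, 77 were on only in them, against 8 off only in them. Another choice of 1 library per group gave at most 63, with a median of 12 over 26 choices. Those libraries were picked for their low r over the same counts, so some excess follows from the choice. Nano-patrol+NIR 3 alone held 41 of the 77. The libraries apart also had TMM factors of 1.047 to 1.113, against 0.935 to 0.99 for the others. They held 19108 to 19394 genes with a count, against 18467 to 18909, so broader detection could also give genes on only in them. Differences in injury between animals and technical differences other than depth were not tested and stay open, as does a sample from outside these groups.

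The number of genes separating rt-PA from the other groups rested on rt-PA 1 and rt-PA 2. With saline 1 in the place of rt-PA 3, limma-voom with library weights called 6664 genes, close to the 6956 of the real groups, so such weights mostly compare rt-PA 1 and 2 with saline 2 and 3. Of the 6710 genes called without the libraries apart, 6647 were among those tested over all libraries, and on them rt-PA 3 had a median position of 0.24 between saline (0) and rt-PA (1), close to the 0.28 of saline 1 and the 0.3 of Nano-patrol+NIR 3. The quartiles were wide, -0.21 to 0.7 for rt-PA 3 and -0.21 to 0.84 for saline 1. For Nano-patrol+NIR against rt-PA, positions ran from rt-PA (0) to Nano-patrol+NIR (1) on 6143 genes chosen likewise. There rt-PA 3 lay at a median of 0.92, Nano-patrol+NIR 3 at 0.89 and saline 1 at 0.79. Quartiles were again wide, 0.47 to 1.34 for rt-PA 3 and 0.25 to 1.29 for saline 1. A response absent from rt-PA 3 remains possible, but with 1 library it cannot be told apart from a technical or tissue difference of that library.

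The smaller difference between Nano-patrol+NIR and saline was looked for in the libraries left out, on genes from 1 choice of libraries, which gave 501 calls. Another choice without rt-PA 3 gave 105, and the other 7 gave 0 or 1. On 499 of the genes called between Nano-patrol+NIR 1 and 2 and saline 2 and 3, Nano-patrol+NIR 3 had a median position of 1.09 between saline (0) and Nano-patrol+NIR (1), and saline 1 of 0.31. The quartiles overlapped, at 0.71 to 1.45 for Nano-patrol+NIR 3 and -0.22 to 0.93 for saline 1. As a hypothesis, a treatment difference may be shared by the 3 Nano-patrol+NIR libraries. rt-PA 3 lay at 1.2 on the same genes, so a difference common to both treatments, or the likeness of rt-PA 3 and Nano-patrol+NIR 3, stays open.

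Other splits of the libraries were fitted beside the real one. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For rt-PA against saline, 2 of 10 splits gave as many edgeR calls as the real 1, the highest other being 15 with rt-PA 1, rt-PA 2 and saline 1 together. For Nano-patrol+NIR against saline 1 of 10 did, the real split with 1 call, and the highest other had 0, although 1758 genes had an unadjusted p under 0.05 in another split, against 907. For Nano-patrol+NIR against rt-PA 10 of 10 did, with 0 calls in the real split and 1 as the highest other. The numbers of genes at an unadjusted p under 0.05 were also exceeded by another split, at 3085 against 2621 for rt-PA against saline and 2687 against 2121 for Nano-patrol+NIR against rt-PA. In the test of any group, 18 of 100 splits of the 9 libraries gave at least the real 1 call, so chance is not excluded for this count, and the highest other called 859, which points to a structure of the libraries other than the groups. With DESeq2, the split with rt-PA 1, rt-PA 2 and saline 1 together called 1507 genes, more than the 1062 of the real groups over the same filtered genes. The real split was the highest with DESeq2 for Nano-patrol+NIR against rt-PA, at 627 against 610, while for Nano-patrol+NIR against saline a mixed split had 144 against 132. With library weights the real split was the highest for rt-PA against saline, at 6956 against 6664, and for Nano-patrol+NIR against saline, at 909 against 540, but not for Nano-patrol+NIR against rt-PA, at 6027 against 6477.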
